A study of Mus musculus with 2 samples.

How the data were processed

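Small RNA under 30 bases was sequenced from skeletal muscle of mice at postnatal day 0, in 2 libraries from 1 pup each, per the labels. The samples form 1 group (replicates 1 and 2, numbered by the labels), and the labels list separate tissue samples but the same donor record for both. That the samples come from 2 pups is therefore an assumption, on which the name of the biological coefficient of variation rests. No sex was recorded.

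For each library the authors deposited a table of raw counts for 1973 microRNA genes, in whole numbers, with 4 further rows for reads that name no gene. Per the readme text deposited with each table, the assembly was mm10 and the gene annotation GENCODE M4. The aligner and counting program are not given in the sources used here. Each table has 3 columns of counts, read as reads on either strand, on the annotated strand and on the opposite strand, since for all 1973 genes the strand columns add up to the first. The sums do not tell the strand columns apart. The column holding most of the counts was taken as the annotated strand, an inference from the values that the sources used here do not state. The annotated-strand counts were used, and the opposite-strand counts enter the closing section, the figure of the Dlk1-Dio3 domain and the alternatives with unstranded counts or with opposite-strand counts assigned. Reads that fit more than 1 place were set apart by the authors (28.01% and 26.9% of reads in replicates 1 and 2), as were unmapped reads (16.0% and 13.3%) and reads in no gene (1.60% and 1.43%). A gene with near-identical copies therefore holds only the reads that fit it alone. These 4 rows stayed out of library sizes and tests. The planned composition by RNA class could not be made, since the tables hold microRNA genes alone, and these read categories took its place.

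Symbols, coordinates and gene context were taken from GENCODE M21 on GRCm38, of which mm10 is the same assembly, by gene ID without version. Of 1973 IDs, 1894 matched, 1815 of them with the same version, and the 79 unmatched rows held 1 and 2 counts. Hairpin sequences came from the matching transcripts. A gene was called sharing when 20 bases of its hairpin recur in another annotated microRNA gene that does not overlap it. This held for 79 of the 365 detected genes.

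The lists, named genes, tests and alternatives were fixed before the data were examined. Besides 9 lists on muscle, imprinted domains, families and Hox clusters, 11 lists hold markers of other cell types: cardiac, fibroblast and mesenchymal, smooth muscle, endothelial, erythroid, leukocyte, cartilage, epithelial and skin, neuronal, endodermal and pluripotency. Symbols were matched ignoring case. The planned matching without hyphens was not used, since it joined different genes. Named genes were the 20 with the highest mean CPM, every myomiR and cardiac gene, the up to 3 highest members of every other list, and up to 5 genes per direction with the largest ratio among those past the test with a mean of at least 100 CPM. Other genes are said to have been chosen after their values were seen.

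CPM are counts scaled to each library's total of annotated-strand microRNA counts. Genes with at least 10 counts in both libraries were called detected. Means and SDs are over the 2 libraries. For ratios between libraries, library sizes were scaled by TMM (factors 1.09 and 0.918, edgeR 4.0.16 in R 4.3.3). Each gene was tested by an exact two-sided binomial test (scipy 1.17.1) with Benjamini-Hochberg adjustment at 0.05 and a fold minimum of 2, with 95% exact counting intervals. List medians were set against 10000 random lists, matched on mean expression in 10 bins for shifts. Random genes were drawn from all detected genes, those of the list included, as if independent. Neighbouring members of a list are not independent, so the percentiles are descriptions and not tests. The biological coefficient of variation came from edgeR's common dispersion with an intercept-only design. Trends on GC content used lowess (statsmodels 0.14.6). Tables were handled with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and plots drawn with matplotlib 3.10.9.

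The test was checked on simulated libraries with the real means and sizes and 200 genes changed. With counting noise alone, 4.65% of 172 unchanged genes passed the adjusted p and 0% the 2-fold test, while 98.0% of 50 genes raised 3-fold and 97.8% of 46 lowered 3-fold passed it. With a biological coefficient of variation of 0.2 added, 78.7% and 89.6% did, and with 0.3, chosen after the measured value was seen, 63.3% of 49 and 86.0% of 43. The adjusted p alone was passed by 58.1% and 66.5% of unchanged genes. Simulated coefficients of 0.1, 0.2 and 0.4 over 365 genes were recovered as 0.0991, 0.198 and 0.409.

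Alternatives were unstranded counts, count minimums of 1 and 50, DESeq2 1.42.0 size factors, library totals, pseudocounts of 0.1 and 10 CPM around the 1 CPM used, a fold minimum of 1.5, each replicate left out, shares without the most abundant gene, genes without shared stretches, and the coefficient of variation in the more abundant genes. After the data were seen, the assignment of opposite-strand counts to the gene annotated there and a split of the epithelial and skin list were added. PCR reads are not independent molecules, so intervals cover counting error only.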

Results

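MicroRNAs, short RNAs that pair with messenger RNAs and lower their output, were profiled in skeletal muscle of newborn mice. RNA under 30 bases was sequenced from 2 samples of strain B6NCrl at postnatal day 0, each a piece of muscle from 1 pup and labelled as a separate biological replicate. They were taken to come from 2 pups, although both carry the same donor record. Both samples belong to 1 group, so no condition was compared with another. The values below describe the microRNA genes of this tissue and how far the 2 libraries differed. Replicate 1 held 16398945 reads and replicate 2 held 21037937. Of these, 7955914 (48.5%) and 10816295 (51.4%) were counted on the annotated strand of 1 of 1973 microRNA genes. At this depth, 3 counts corresponded to 0.377 CPM (counts scaled to the library's total of microRNA counts) in replicate 1 and 0.277 CPM in replicate 2. Intervals and floors cover counting error only.

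Ranks and shares from here on use annotated-strand counts of reads that fit 1 place, except where stated. Reads shared by near-identical copies are therefore missing, and opposite-strand counts were left out. Those at Gm25301, opposite Mir378a, would rank 2 with 5.61% of the counts of both strands. Among annotated-strand counts, the muscle-specific microRNA gene Mir206 was the most abundant, with 113917 CPM ± 9579 (SD, n = 2), 11.4% ± 0.958 of them. It lies at chromosome 1, 20679010 to 20679082 (GRCm38), in an exon of the noncoding gene Gm28653. Next among annotated-strand counts came 3 genes of the imprinted Dlk1-Dio3 domain on chromosome 12. They were Mir487b with 60149 CPM ± 7818, Mir411 with 53446 ± 5728 and Mir381 with 50135 ± 2423 (SD, n = 2). Mir335, in an intron of the imprinted gene Mest, followed with 48999 CPM ± 12855, and Mir126a, in the endothelial gene Egfl7, with 46207 ± 1727. Mirlet7i had 44577 CPM ± 249, Mir431 41009 ± 11258, Mir127 37389 ± 346 and Mir143 29128 ± 1961 (SD, n = 2).

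The 10 most abundant genes of each library took 52.5% ± 2.38 of its counts, and 90% of counts fell on 55 genes in replicate 1 and 51 in replicate 2. The next 10 genes by mean CPM began with Mirlet7g (28228 ± 882), Mir99a (26445 ± 1939) and Mir322 (25226 ± 2016). Below these stood Mir434 (18904 ± 3138), Mir379 (18710 ± 2423), Mir23a (18218 ± 852) and Mir26b (17835 ± 2271). Mir22 (14837 ± 471), Mir23b (13720 ± 99.8) and Mir130a (11513 ± 1585) closed the first 20. Mir23a and Mir23b share a stretch of 20 bases with each other, as Mir487b and Mir411 do with other members of their domain, so their single levels are uncertain. At least 10 counts in both libraries were found for 365 of the 1973 genes (18.5%), while 1255 genes had 0 counts in both.

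Of the muscle-enriched microRNAs (myomiRs), fixed as a list of 8 genes, 7 were detected and together took 11.6% ± 0.951 of counts (SD, n = 2). Mir206 alone carried almost all of it, since the list held 0.236% of the counts that remained without that gene. Mir133b, beside Mir206 on chromosome 1 at 20682769 to 20682887, had 832 CPM ± 12.6. Mir206 exceeded it 137-fold ± 13.6, an upper limit, because Mir133b shares a 20-base stretch with Mir133a-1 and Mir133a-2. Mir208b, in an intron of the slow myosin gene Myh7, had 747 CPM ± 21.6, and Mir499, in an intron of Myh7b, had 493 ± 72.9. The level of Mir208a, in an intron of the cardiac myosin gene Myh6 and the single gene of the cardiac list, was 13.8 CPM ± 2.37. Mir208b therefore exceeded Mir208a 55.2-fold ± 11.04 (SD, n = 2). The remaining myomiR genes, each of which also shares such a stretch with a copy, stood far lower: Mir1a-1 had 8.26 CPM ± 2.53, Mir133a-1 5.73 ± 0.255, Mir1b 1.78 ± 0.685 and Mir133a-2 1.18 ± 0.424, the last from 7 and 16 counts. Reads that fit more than 1 place were set apart before counting and made up 28.01% of reads in replicate 1 and 26.9% in replicate 2. The counts of these 4 genes and of Mir133b are therefore a lower limit. Mir486, a muscle and erythroid microRNA in an intron of Ank1, had 74.8 CPM ± 11.2. Mir3107 is annotated on its other strand. Overlapping genes were left out of the search for shared stretches, so whether reads of Mir486 also fit Mir3107 was not checked. If they do, the level of Mir486 is a lower limit too.

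Genes of the Dlk1-Dio3 domain, whose microRNAs are expressed from the maternal chromosome, took 36.9% ± 3.55 of all counts. This was the largest share of the 20 lists among reads that fit 1 place. Reads set apart for fitting more than 1 place equalled 0.577 and 0.523 of the annotated-strand microRNA counts in replicates 1 and 2. To which lists those reads belong is not known, so the order of lists with them included stays open. Of 52 members in the tables, 48 were detected, 30 stood above 1000 CPM and 7 were among the 20 most abundant genes. They span chromosome 12 from 109563692 to 109747960 (GRCm38), 184.3 kb. The median rank of the detected members was 82.1 on a scale of 0 to 100 among detected genes, at percentile 100 of 10000 random lists of the same size. Without the genes that share a 20-base stretch, the domain's share was 30.35%.

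**Figure D1:**
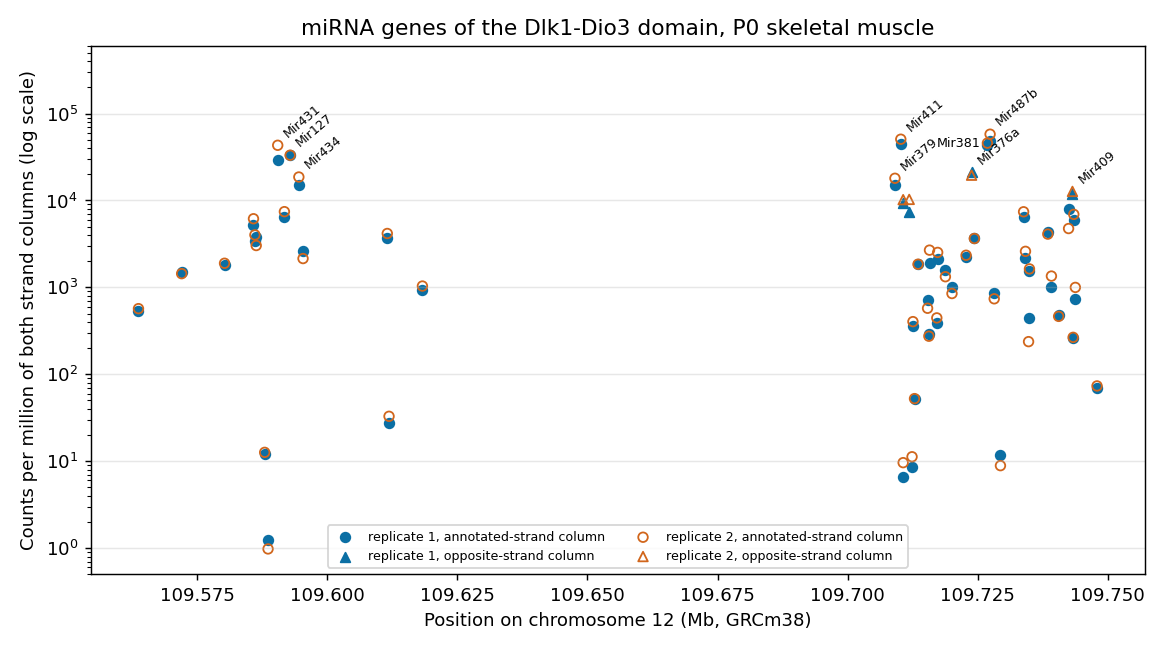
CPM (log scale), scaled here to the counts of both strand columns together and so lower than the CPM in the text, for the microRNA genes of the Dlk1-Dio3 domain against position on chromosome 12 (Mb, GRCm38), filled symbols for replicate 1 and open symbols for replicate 2. Circles are counts on the annotated strand, triangles are counts on the opposite strand of a listed gene, drawn at the gene annotated there, and genes with 0 counts are not drawn.

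The let-7 family, which accumulates as tissues mature, was the third largest list in these counts with 9.22% ± 0.128 of them (SD, n = 2). All 10 members were detected, and 5 of them share a 20-base stretch and hold only the reads that fit 1 place. Mirlet7i, Mirlet7g and Mirlet7d (9364 CPM ± 729) led the family. Mirlet7i exceeded the sum of Mirlet7a-1 and Mirlet7a-2 279-fold ± 112, an upper limit, since both Mirlet7a genes share sequence and hold only the reads that fit 1 place. The chromosome X cluster of Mir322 and Mir503, linked to muscle differentiation, took 3.94% ± 0.398, with Mir322, Mir351 (8861 CPM ± 1596) and Mir542 (2794 ± 20.9) as its highest members. MicroRNAs within Hox clusters took 2.37% ± 0.154, led by Mir196b (11049 CPM ± 1571), Mir10b (8799 ± 261) and Mir10a (1891 ± 71.0). The proliferation-linked miR-17-92 family and its paralog clusters took 0.892% ± 0.273, led by Mir17 (3717 CPM ± 1342), Mir20a (1112 ± 458) and Mir93 (1031 ± 403). From the imprinted Igf2-H19 region, Mir483, in an intron of Igf2, had 7520 CPM ± 17.1 and Mir675, in an exon of H19, 117 ± 3.56. The ratio of the pair was 64.3 ± 2.10, and the list took 0.764% ± 0.00136.

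Other microRNAs linked to muscle formation took 0.312% ± 0.00559 of counts, with 10 of 13 detected. Mir27b had 1836 CPM ± 59.5, Mir181a-1 720 ± 96.4 and Mir181b-2 186 ± 148 (SD, n = 2), and all 3 share sequence with a paralog, so these are lower limits. Without genes that share a stretch, the list took 0.02544%. The share of the whole list was 5.885% when counts on the opposite strand were assigned to the gene annotated there, an alternative chosen after seeing the data, because Mir378a then entered the list.

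Among lists for other cell types, the endothelial and smooth muscle genes took the largest shares. Mir126a, the single endothelial gene, took 4.62% ± 0.173 of counts. The smooth muscle genes took 3.002% ± 0.214, with Mir143 33.1-fold ± 4.41 above its neighbour Mir145a (890 CPM ± 177), while Mir145b had 1 and 0 counts. The fibroblast and mesenchymal genes took 0.587% ± 0.120, with Mir214 at 4891 CPM ± 759, Mir199b at 880 ± 397 and Mir199a-2 at 87.0 ± 42.5. Of these 4 genes, 3 share a 20-base stretch with a paralog, so the share is a lower limit. In the endothelial and smooth muscle lists 0 detected genes share one. The order of lists by share therefore holds for these counts only. Cartilage genes took 0.209% ± 0.0168, from Mir140 in the gene Wwp2 (1165 CPM ± 130) and Mir455 in Col27a1 (922 ± 38.0). Neuronal genes took 0.107% ± 0.00387, with Mir128-1 at 456 CPM ± 41.1, Mir128-2 at 389 ± 48.9 and Mir132 at 121 ± 8.70. Mir128-1 and Mir128-2 share a 20-base stretch with each other, and the neuronal share was 0.02279% without genes that share one.

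Blood-cell genes were low. Leukocyte genes took 0.0649% ± 0.0146 (SD, n = 2), with the myeloid Mir223 at 465 CPM ± 88.2, Mir146 at 93.4 ± 35.3 and the lymphocyte gene Mir150 at 45.5 ± 0.692. The leukocyte share became 0.124% when opposite-strand counts were assigned to the gene annotated there, as Mir142 was then counted. Erythroid genes took 0.0434% ± 0.0210, with Mir451a at 404 CPM ± 204 and Mir144 at 30.0 ± 6.53. Epithelial and skin genes took 0.0433% ± 0.0139, with Mir203 at 280 CPM ± 16.6, Mir429 at 54.5 ± 50.7 and Mir200c at 35.8 ± 33.6. Endodermal genes took 0.0218% ± 0.00464, with the liver microRNA Mir122 at 120 CPM ± 47.2, Mir192 at 50.9 ± 2.67 and Mir194-2 at 25.3 ± 5.30. Of 12 pluripotency genes, only Mir302d was detected at the count minimum, with 13 counts in each library. Mir302a (9 and 16 counts) and Mir294 (8 and 9 counts) fell under it, and the list took 6.40e-04%. The cardiac and miR-486 lists, of 1 gene each, took 0.00138% and 0.00748%. The limit given above for Mir486 holds for its list.

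**Figure D2:**
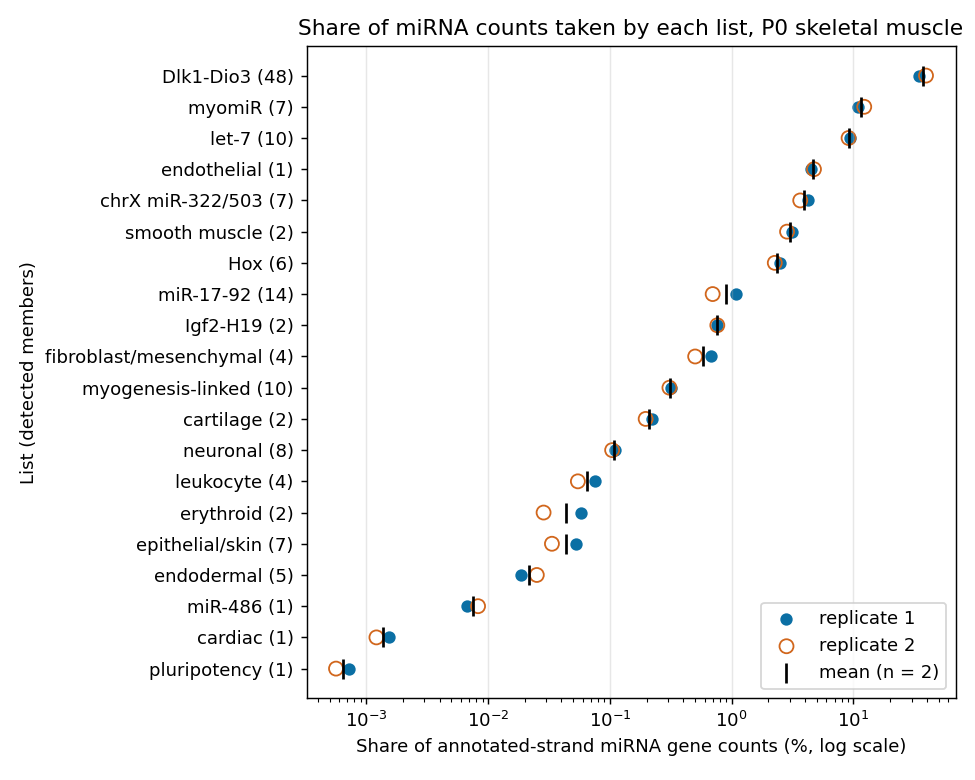
Share of annotated-strand microRNA gene counts (%, log scale) taken by each of 20 gene lists, filled circles for replicate 1, open circles for replicate 2 and bars for the mean of both (n = 2), with the number of detected members in brackets. The shares run from 36.9% for the Dlk1-Dio3 domain to 6.40e-04% for the pluripotency list.

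Levels of the 365 detected genes followed each other closely between the 2 libraries, from Mir206 at the top to Mir302d near the bottom. Across genes, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.992 and Spearman's rho was 0.989. The median absolute log2 ratio was 0.31 after trimmed-mean (TMM) scaling, and 90% of genes lay within 0.91. The biological coefficient of variation, estimated by edgeR with 1 residual degree of freedom per gene pooled over genes, was 0.257 (0.228 to 0.283 over 100 bootstrap draws of genes). TMM in place of library totals moved each log2 ratio of replicate 1 over replicate 2 by -0.25, and ratios below use TMM. Among the most abundant genes, the ratio was -0.42 for Mir206, -0.81 for Mir431, 0.30 for Mir335 and -0.32 for Mir126a, less than 2-fold in each case.

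Between the libraries, 23 genes were higher in replicate 1 and 4 were higher in replicate 2 by at least 2-fold with an adjusted p under 0.05 (exact two-sided binomial test, Benjamini-Hochberg over 365 genes). With library totals the split was 41 and 1. This test compares the 2 libraries and not conditions, and counting error is its only error term. In simulated libraries with biological coefficients of variation of 0.2 and 0.3, below and above the measured value, 2.91% of 172 and 12.1% of 173 unchanged genes passed it, against 27 of 365 genes in the real libraries. The measured value came from these same 2 libraries. The comparison therefore cannot tell whether the 27 genes exceed usual differences between samples.

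Of the genes with a mean of at least 100 CPM, 3 passed. Mir181b-2 at chromosome 2, 38853830 to 38853918, had 291 CPM in replicate 1 and 80.9 in replicate 2, a log2 ratio of 1.60 (95% counting interval 1.49 to 1.71). Mir16-2, in an intron of Smc4 on chromosome 3, had 254 and 99.7 CPM, a ratio of 1.10 (1.00 to 1.21). The liver-enriched Mir122 on chromosome 18 was higher in replicate 2, with 86.3 and 153 CPM and a ratio of -1.07 (-1.20 to -0.94). That ratio was -0.83 and no longer 2-fold under library totals, and it was also under 2-fold with a count minimum of 1. Both Mir181b-2 and Mir16-2 share sequence with a paralog. The 3 other genes higher in replicate 2, Mir592, Mir504 and Mir3475, were picked out after their values were seen and had at most 15.2 CPM in either library. Their ratios were -1.32, -1.09 and -1.04.

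**Figure D3:**
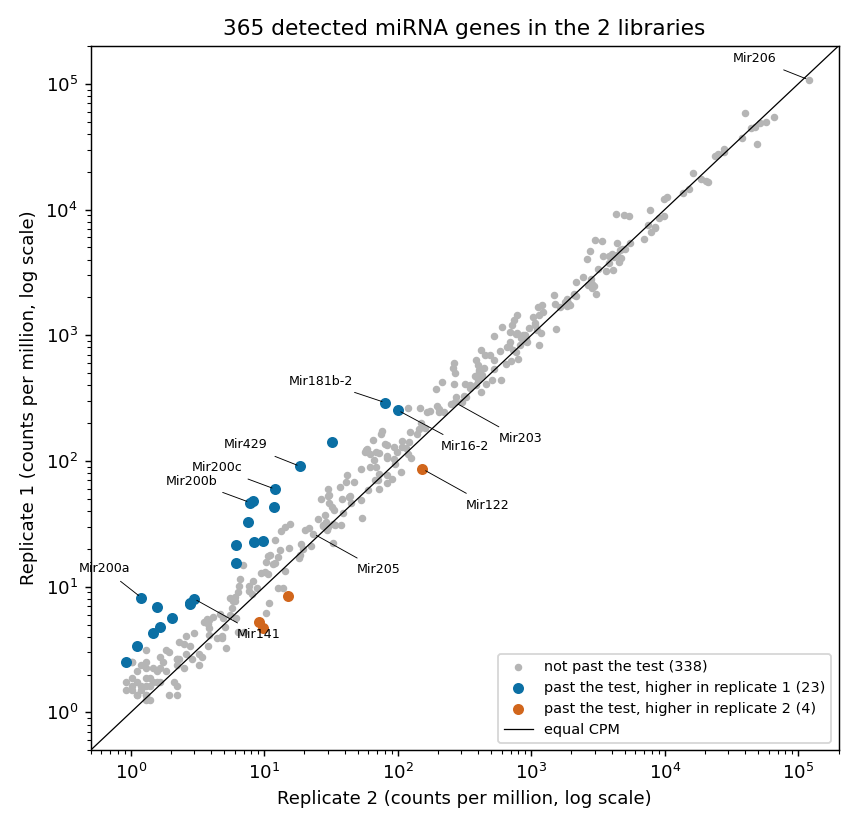
CPM in replicate 1 against replicate 2 (both log scale) for the 365 detected microRNA genes, with the line of equal CPM. Blue points mark the 23 genes past the test and higher in replicate 1, orange points the 4 higher in replicate 2, called on TMM-scaled ratios and not on the CPM drawn.

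The epithelial and skin list differed most between the 2 samples. Its 5 miR-200 family genes, typical of epithelial cells, were all higher in replicate 1, with log2 ratios of 2.52 for Mir200a, 2.32 for Mir200b, 2.05 for Mir200c, 2.03 for Mir429 and 1.20 for Mir141. The keratinocyte microRNAs of the same list, Mir203 and Mir205, had ratios of -0.12 and -0.07 with TMM and a median of 0.15 under library totals. Mir200a, Mir200b and Mir429 lie together on chromosome 4 in an intron of Ttll10, and Mir200c and Mir141 together on chromosome 6. Mir200a, Mir200b, Mir141 and Mir205 were named after their values were seen. The list's median ratio was 2.03, at percentile 100 of 10000 random lists matched on expression, whose medians lay between -0.32 and 0.71 in 95% of draws. Random lists treat genes as independent, while the 5 miR-200 genes are neighbours on chromosomes 4 and 6, so the percentile is a description only.

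The miR-17-92 list leaned the same way, with a median ratio of 0.54 (percentile 99.8) and 12 of its 14 detected members above 0. Of these, 9 passed the adjusted p (exact binomial test) both over all genes and adjusted over the list alone, near the share of 223 of 365 among all detected genes, and 3 passed the 2-fold test. Mir17 (0.51), Mir20a (0.62) and Mir93 (0.57) stayed under 2-fold. Many members of the miR-17-92 list are neighbours too, so its percentile has the same limit. The fibroblast and mesenchymal list had a median of 0.64 (percentile 99.4) with all 4 members above 0, but 3 of the 4 share sequence. Without such genes, Mir214 alone remained at 0.12.

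Genes of the Dlk1-Dio3 domain leaned towards replicate 2, with a median log2 ratio of -0.35, below each of the 10000 matched random lists. The members are neighbours in 1 domain, while random lists treat genes as independent. The comparison and the counts of members below therefore rest on observations that are not independent. Of 48 members, 41 were below 0, and 38 passed the adjusted p in that direction against 4 in the other (exact binomial test, 42 also when adjusted over the list alone), where 223 of all 365 detected genes passed it in either direction. Counting error is the only error term of this test, so abundant genes pass it more readily. The members had a median rank of 82.05 on the scale of 0 to 100, so the share over all detected genes is no matched comparison. How many members passed under library totals was not counted. No member reached 2-fold. Under library totals the median was -0.11 and 33 of 48 were below 0. Mir487b had a ratio of -0.51, Mir411 of -0.46 and Mir381 of -0.34.

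For the remaining lists the shift lay inside or at the edge of the range of 95% of the random lists. The medians were -0.15 for the myomiRs, which became 0.09 under library totals, and -0.55 for Mir486, 0.11 for Mir208a, 0.10 for the other muscle-linked genes and -0.10 for the chromosome X cluster. They were -0.27 for Igf2-H19, 0.08 for let-7, -0.06 for Hox and 0.03 for smooth muscle. Endothelial Mir126a stood at -0.32, erythroid genes at 0.52, leukocyte genes at 0.34 and cartilage genes at -0.09. The medians of neuronal, endodermal and pluripotency genes were 0.07, -0.30 and 0.20. Mir451a (548 and 260 CPM, ratio 0.83) passed 2-fold only under library totals.

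**Figure D4:**
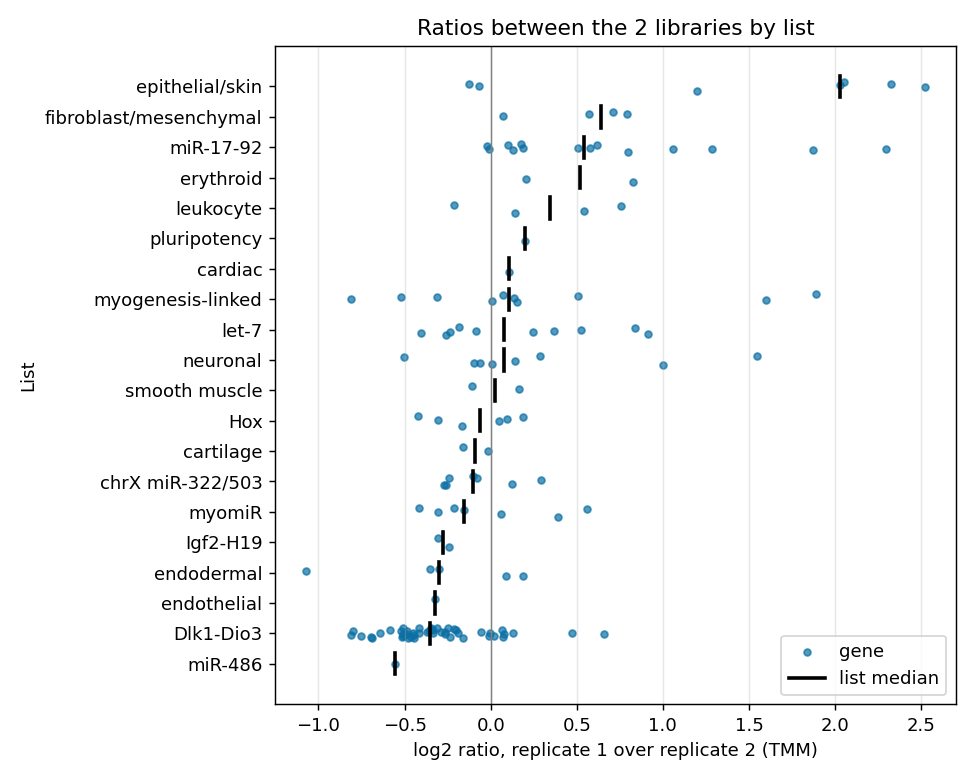
Log2 ratios of replicate 1 over replicate 2 (TMM scaling) for the detected genes of each list, 1 point per gene spread vertically at random, with the list median as a black bar. The epithelial and skin list has the highest median, 2.03, and Mir486 the lowest, -0.55.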

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

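The tests on the strand of counts, on shared reads between copies and on skin in replicate 1 were chosen after the results were seen. The predictions of both tests on GC content are recorded as written beforehand, although the patterns they address were known only from the results. The design gives a single group, so, apart from skin in the sample of replicate 1, no biological explanation was tested.

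Opposite-strand counts, which the comparisons leave out, stood above 3 in both libraries at 24 genes. At 13 of these they outnumbered the annotated-strand counts. Summed over both libraries, Gm25301, opposite Mir378a at chromosome 18, 61397835 to 61397900, held 1204177 counts, 5.61% ± 0.679 of the counts of both strands (SD, n = 2). With that level it would rank as gene 2 by reads that fit 1 place. The genes opposite members of the Dlk1-Dio3 domain were Gm25252 (Mir376a, 427373 counts), Gm24321 (Mir409, 261703), Mir299b (Mir299a, 208806) and Gm25750 (Mir380, 192572). Lower counts stood at Gm25927 (opposite Mirlet7e, 51339), Gm24083 (Mir191, 36388), Mir142b (Mir142, 13592), Mir497b (Mir497, 11206) and Gm24111 (Mirlet7f-1, 3115). The last were Mir3074-1 (Mir24-1, 550), Mir1b (Mir1a-2, 297) and Gm25641 (Mir9-1, 10). At the other 11 genes the opposite strand held fewer counts: Mir337 (718), Mir3071 (436), Mir486 (130), Mir203 (80), Mir434 (52), Mir126a (47), Mirlet7b (38), Mir127 (29), Mir338 (28), Mir7654 (10) and Mir708 (9).

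The 13 genes were selected for more counts on the opposite strand in both libraries, so that excess itself is no evidence. Leakage of reads to the wrong strand is argued against by size, for the 13 genes together. They held 235 and 277 annotated-strand counts in replicates 1 and 2, and 99.92% and 99.94% of all opposite-strand counts. Over the remaining 1960 genes, from which the selected ones were left out, opposite-strand counts were 0.00904% of annotated-strand counts. All 13 overlap a GENCODE M21 microRNA gene on the other strand that has no entry of its own in the tables, against 19 of the remaining 1960 genes (Fisher's exact test, two-sided p = 3.278e-25). A candidate explanation is that these are reads of the genes on the other strand.

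Reads that fit more than 1 place, also left out, made up 27.45% ± 0.799 of reads (SD, n = 2). In most clusters, genes with a near-identical copy had fewer counts than their neighbours. In 17 of 20 genomic clusters (same strand, gaps up to 10 kb), members that share a 20-base stretch lay below members that do not, with a median difference of -5.15 in log2(CPM + 1) (exact sign test, two-sided p = 0.00258). Mir133b, for example, differed from Mir206 by -7.10, while 3 clusters went the other way: the largest, 31 genes from Mir379 with Mir411 and Mir487b among its sharing members (3.14), Mir26a-2 (5.36) and the one from Mir466b-3 (0.564). Hairpin GC content as the whole cause is argued against, since the difference was -5.16 after a trend on GC was removed, in 16 of 20 clusters (exact sign test, two-sided p = 0.0118). Some sharing members of different clusters are copies of each other, such as Mir16-1 and Mir16-2. The 20 clusters are therefore not independent, and both sign tests overstate the evidence. Loss of shared reads may account for part of the low counts of Mirlet7a-1, which lay below Mirlet7d in its cluster. The clusters did not hold Mir1a-1, Mir133a-1 or Mir26a-1, so for these the comparison shows nothing. Lower true levels of some copies stay open and untested.

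The 5 miR-200 genes had a median log2 ratio of 2.05 (replicate 1 over replicate 2), from 1693 counts in replicate 1 and 463 in replicate 2. Skin that raised Mir203 and Mir205 of keratinocytes about as much as the miR-200 genes is argued against. Their median was -0.095 with upper counting bounds of -0.05 and 0.20, and 0.15 under library totals. In replicate 2, however, Mir203 (268 CPM) and Mir205 (23.3) stood above all 5 miR-200 genes, of which Mir429 was highest (18.7). The same added CPM would give them smaller ratios, so a smaller contribution of skin stays open. In replicate 1, Mir205 had 26.4 CPM and Mir429 90.4. A trend on hairpin GC as the whole cause is argued against, since the median stayed at 2.02 after it was removed. Epithelial cells other than keratinocytes in the piece of muscle, or another difference between the samples, also stay open, and neither was tested.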

How the results depend on the processing

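The assignment of opposite-strand counts and the split of the epithelial list were chosen after seeing the data. Of 64 named genes with a ratio, 56 kept their side of the test under each alternative that held them. With a fold minimum of 1.5, Mir431, Mir434, Mir20a, Mir199b, Mir451a and Mir199a-2 passed it as well. Mir199a-2 and Mir451a passed the 2-fold test under library totals, and Mir1b with unstranded counts. Mir122 no longer passed under library totals or with a count minimum of 1. With a count minimum of 1, 591 genes were detected, Pearson's r was 0.994 and Spearman's rho 0.971, and r was 0.989 with a minimum of 50. Mir206 took 10.1% and the top 10 genes 49.6% of counts when strands were pooled or opposite-strand counts assigned, and 13.7% and 55.9% without genes sharing a stretch. The myomiR share was 10.3%, 10.3% and 13.8% in these settings and 0.236% without Mir206, which removes its main member, and the Dlk1-Dio3 share was 41.7% without Mir206 and 30.35% without sharing genes. Median ranks with either replicate left out ranged from 51.4 to 68.8 for the myomiRs and from 82.6 to 84.1 for Dlk1-Dio3, which stood at 88.9 and 77.5 with minimums of 1 and 50 and at 79.2 without sharing genes. Replicate 2 alone adds Mir133a-2 (16 counts) to the detected myomiRs. Genes higher in replicate 1 numbered 13 with a minimum of 50, 41 with library totals, 15 without sharing genes and 52 with a fold minimum of 1.5. Those higher in replicate 2 numbered 2 with a minimum of 1, 2 with a minimum of 50, 1 with library totals and 20 with a fold minimum of 1.5. The coefficient of variation was 0.297 with library totals and 0.204 in genes above the median CPM. Library totals shift all ratios alike, and this turned the list medians of myomiRs (0.091), the chromosome X cluster (0.14), Hox (0.18) and cartilage (0.16), while those of Dlk1-Dio3 (-0.11) and miR-17-92 (0.79) kept their sign. Other turns were let-7 without sharing genes (-0.18), Hox with a minimum of 1 (0.022) and miR-203 and miR-205 alone (-0.095), and Dlk1-Dio3 was -0.27 with a minimum of 1. Except where stated, the cause was not tested. No paired analysis was possible because there is 1 group. Depth limits genes near 10 counts, and the pluripotency list gave no value at a minimum of 50.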

Other observations

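The genes in this part were named after their values were seen. Besides the miR-200 family, 3 genes of a cluster on chromosome 6 were higher in replicate 1: Mir182 had 140 CPM in replicate 1 and 31.9 in replicate 2 (log2 ratio 1.89, counting interval 1.72 to 2.07), Mir96 43.4 and 11.9 (1.62), and Mir183 77.7 and 41.3 (0.67, under 2-fold). On chromosome X, Mir106a (47.9 and 8.23 CPM, ratio 2.30) and Mir20b (32.9 and 7.58, ratio 1.87) were higher in replicate 1, each by more than 2-fold. Of the other detected members of that cluster, Mir363 had 29.7 and 14.4 CPM (ratio 0.79, interval 0.50 to 1.10), Mir18b 2.51 and 1.02 (1.06, -0.07 to 2.27) and Mir92-2 43.1 and 31.9 (0.19, -0.03 to 0.41).

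Neighbouring members of the miR-181 family differed in opposite directions between the libraries. Mir181b-1 and Mir181b-2 had ratios of 1.89 and 1.60, while Mir181a-1 had -0.52 and Mir181a-2 had -0.81. All 4 share a 20-base stretch with a paralog. In the let-7 family, the 5 members that share a stretch had ratios between 0.24 for Mirlet7f-2 and 0.92 for Mirlet7c-2, and the 5 that do not had ratios between -0.40 for Mirlet7d and -0.09 for Mirlet7b. These ratios use TMM. Library totals shift them all upward alike, which puts some of the latter 5 above 0 but leaves both miR-181a genes below it. Over all detected genes, the median was 0.20 for the 79 that share a stretch and -0.01 for the 286 that do not.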
